A study of Caenorhabditis elegans with 12 samples.

How the data were processed

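Small RNA was taken from 12 samples of adult whole animals grown at 20 °C, 3 for each of 4 groups (control or hrde-2 strain, L4440 or oma-1 dsRNA). Per the labels' protocols, small RNAs were enriched with a mirVana kit, 2 µg were cloned by a method that does not need a 5′ monophosphate, libraries carried a 5′ barcode of 4 nt and a 3′ barcode of 6 nt, and sequencing was on a NextSeq500. HTSeq 0.6.1 is the only processing tool that the labels name. The aligner, genome build, annotation, strand setting and treatment of reads that match several places are not given in the sources used here.

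The deposited table gives raw read counts per WormBase gene identifier, per the file headers, in 1 column per group. A second block of columns holds a normalized signal, which the authors obtained by dividing the count by 1 constant per column, 1 in control on L4440, 1.34 in control on oma-1, 2.33 in hrde-2 on L4440 and 0.87 in hrde-2 on oma-1. The file headers name library size for it, without saying how that size was counted. How the 3 samples of a group were merged is not given in the sources used here. Because each group has 1 column, the fit of 4 groups planned before the data were examined has no residual degree of freedom, so that the edgeR and DESeq2 tests of the single-food, single-genotype and interaction contrasts, permutations, a replicate block and leaving out each replicate could not be used. These differences are given as ratios with counting intervals. After the data had been seen, an additive fit of genotype and dsRNA, which leaves 1 residual degree of freedom, was added for the effects averaged over the other factor, with glmQLFit (robust) and glmQLFTest of edgeR, DESeq2 1.42.0, and camera and fry of limma on voom values. Its common dispersion was 0.0305, and the spread was shared across features almost wholly, since the prior degrees of freedom were at least 453.

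Reads assigned to genes made up 38.7% of all reads listed in control on L4440, 40.1% in control on oma-1, 34.7% in hrde-2 on L4440 and 34.8% in hrde-2 on oma-1. Ambiguous reads made up 41.3, 40.4, 41.1 and 42.4%, reads at no annotated feature 17.8, 17.6, 21.4 and 20.6%, and reads not aligned 2.19, 1.92, 2.76 and 2.20%. Reads without a gene were not used in the comparisons. Of 46726 identifiers, 46364 matched an annotation of build WBcel235, from which positions and gene classes were taken, and 362 did not.

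Features were kept by filterByExpr of edgeR with its default minimum count of 10 and total of 15, which left 16329 features and removed 30397. TMM factors were computed on these. Relative to control on L4440 the scale was 1.39 in control on oma-1, 4.08 in hrde-2 on L4440 and 1.33 in hrde-2 on oma-1, while gene-assigned totals alone gave 1.35, 1.54 and 0.634. Log2 differences used a prior count of 0.5, scaled to library size. A feature was compared at 5 CPM or more in the higher group, which is 81.8, 113.9, 333.3 and 109.1 reads in the 4 columns, and counted as higher or lower at a difference of 2-fold or more. Ratios carry exact 95% intervals from the conditional binomial (Clopper-Pearson), levels exact Poisson intervals, and shares of reads Wilson intervals.

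Reads that map to more than 1 gene can appear at each of them. A gene was therefore marked as sharing reads where its span overlaps an annotated tRNA, rRNA, snRNA, snoRNA or miRNA, or where another gene had near-equal reads in all 4 columns, within 5% or 15 reads, at 1000 reads or more in total. Of 1269 genes with that many reads, 433 (34.1%) had such a partner, against 7.01% and 5.75% when their reads were multiplied by a constant. This mark was defined after the data were seen. Genes with fewer reads, among them clc-6, could not be marked by near-equal reads. Of the 77 spermatogenesis genes compared, 7 carried the mark for shared reads, among them msp-19, msp-36, msp-51, msp-53 and msp-57.

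Gene lists were fixed before the data were examined: oma-1 with oma-2, neighbours of oma-1, germline nuclear RNAi targets, ERGO-1 26G targets, small RNA pathway, oogenic germline, chromosome segregation, spermatogenesis, early zygotic, intestine, muscle, cuticle collagen, neuronal, histone, F-box, MATH with BATH and BTB, chemoreceptor, C-type lectin, ribosomal protein, mitochondrially encoded, rRNA, miRNA and piRNA genes. The median of each list with 5 or more members was set against 10000 random lists drawn from 20 bins of mean abundance, in place of camera as the main comparison. With no test of spread, and with genes of a family that are not independent, a percentile is a place and not a p-value. The pair oma-1 and oma-2 was too small for this and is given gene by gene.

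Genes named in the text are oma-1, oma-2, hrde-1 and hrde-2 in each comparison, the 12 highest and 12 lowest at 20 CPM or more, and up to 4 list members with the largest difference at that level. This follows the rule fixed before the data were examined without its p-values. Because that rule mostly named structural RNAs, a further rule was added after seeing the data: the 12 highest and lowest at 5 CPM or more among protein-coding genes, pseudogenes and long noncoding RNA genes whose span holds no structural RNA. C38D9.2, R03D7.2 and znfx-1 were named from their lists after their values were seen.

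Other settings tried were median-of-ratios and upper-quartile factors, library size alone with or without oma-1 and oma-2, factors from 40 miRNA genes, no filter, a strict filter of 10 CPM in 3 columns (878 features), only the columns compared, and structural and short RNA genes left out. For the gene lists only library size alone had been planned among these, for the agreement between foods only library size alone and the strict filter, and for hrde-1 and hrde-2 none. Chosen after seeing the data for all results were the authors' factors, the total of all reads listed, the total of protein-coding genes without shared reads, genes with shared reads left out and a minimum of 20 CPM.

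The procedure was tested on simulated counts with 200 changed genes. In the L4440 comparison 34 of 64 genes set to 2-fold, 64 of 64 set to 4-fold and 67 of 67 set to 8-fold were counted, and 0 of 1820 unchanged ones. In the oma-1 comparison these numbers were 34 of 66, 65 of 65, 66 of 66 and 0 of 1812. With no change between the dsRNAs, 0 of 2033 features were counted in control and 0 of 1932 in hrde-2. Of 100 random lists, 9 lay outside the central 95%. The simulation holds counting error alone. The additive fit was tested on counts simulated at its own dispersion, and called 194 of 200 features set to 4-fold and 12 of 16129 unchanged ones. This dispersion was the same for every feature and came from the departure between foods, not from samples of a group. This simulation thus cannot tell how many calls in the data are false. Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 was used, and R 4.3.3 with edgeR 4.0.16 and limma 3.58.1.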

Results

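Small RNAs were sequenced from adult whole Caenorhabditis elegans of 2 genotypes, each fed bacteria making 1 of 2 double-stranded RNAs (dsRNA). The control strain, YY1312, carries hrde-1(gg594), and the mutant strain carries the same allele together with hrde-2(gg517). The sample titles call the control group wild-type, and what the gg594 allele changes in hrde-1 is not given in the sources used here. HRDE-1 is a nuclear Argonaute of the germline that binds small RNAs and is needed for the inheritance of gene silencing. The fed dsRNA matched either oma-1, a gene whose product is a zinc-finger protein of maturing oocytes, or came from L4440, the vector without a worm gene. The cloning, per the labels' protocols, does not depend on a 5′ monophosphate, so that it takes in small RNAs with a 5′ triphosphate, such as the 22G RNAs made by RNA-dependent RNA polymerases. There were 12 samples, 3 in each of the 4 groups: control on L4440, control on oma-1, hrde-2 on L4440 and hrde-2 on oma-1.

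The table held 1 pooled column of read counts per group and no replicates, so that no spread between samples of a group could be measured. Only the genotype effect averaged over foods and the dsRNA effect averaged over genotypes could be tested, in 1 additive fit of the 4 columns; the other differences are given without a test. Intervals cover counting error only, and reads copied by PCR are not independent molecules. Reads assigned to genes numbered 25323188 in control on L4440, 34238988 in control on oma-1, 39077097 in hrde-2 on L4440 and 16057238 in hrde-2 on oma-1. Transfer RNA genes took 59.3, 53.6, 54.5 and 59.8% of these reads in that order of groups, and rRNA genes 14.7, 19.9, 14.8 and 10.3%. Protein-coding genes took 14.02, 14.94, 15.9 and 15.4%, and miRNA genes 0.272, 0.266, 0.7001 and 0.542%. The 95% Wilson interval of each of these shares was at most 0.0480 percentage points wide. Protein-coding genes not marked as sharing reads with a structural RNA or a near-equal gene held 572755, 801129, 1799695 and 625875 reads. Below, genes without shared reads, or unshared genes, are those without this mark. Genes with few reads could not be marked by near-equal reads, and some of them may share reads. Of the 1152 such protein-coding genes compared between genotypes over both foods, 761 had too few reads for that part of the mark. Levels are given as CPM, counts scaled to a common library size with factors from the trimmed mean of M values (TMM). On that scale miRNA genes together stood at 4214, 4001, 4104 and 3986 CPM, so that the larger miRNA share in hrde-2 is not seen under TMM.

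The first comparison asks which genes gained small RNAs when control animals ate oma-1 dsRNA. Reads at oma-1 (WBGene00003864, chromosome IV, 8888976 to 8890999, plus strand, build WBcel235) numbered 37 on L4440 and 10881 on oma-1 dsRNA. That is 2.26 CPM (1.59 to 3.12) against 478 (469 to 487), a ratio of 211 (95% counting interval 153 to 300.1) and a log2 difference of 7.71. In hrde-2 mutants oma-1 had 148 reads on L4440 and 5250 on oma-1 dsRNA, 2.22 CPM (1.88 to 2.61) against 241 (234 to 247). The ratio there was 108 (92.1 to 128.5) and the log2 difference 6.75. In both genotypes oma-1 ranked 1 among the features compared, 2018 in control and 1853 in hrde-2. The next highest was clec-223, a C-type lectin gene, at 1.64 in control, and C27H6.5, a small nucleolar RNA gene, at 1.95 in hrde-2.

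The paralog oma-2 (WBGene00003865, chromosome V, 8029439 to 8031214) did not share this gain at the depth reached. It had 38 reads on L4440 and 66 on oma-1 dsRNA in control, a ratio of 1.247 (0.824 to 1.91), and 126 and 44 reads in hrde-2, a ratio of 1.07 (0.739 to 1.52). Of the 10 protein-coding genes nearest to oma-1, 5 had enough reads to be compared. Their median log2 difference between the dsRNAs was 0.41 in control and −0.41 in hrde-2, both inside the central 95% of random gene lists of like abundance.

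**Figure D1:**
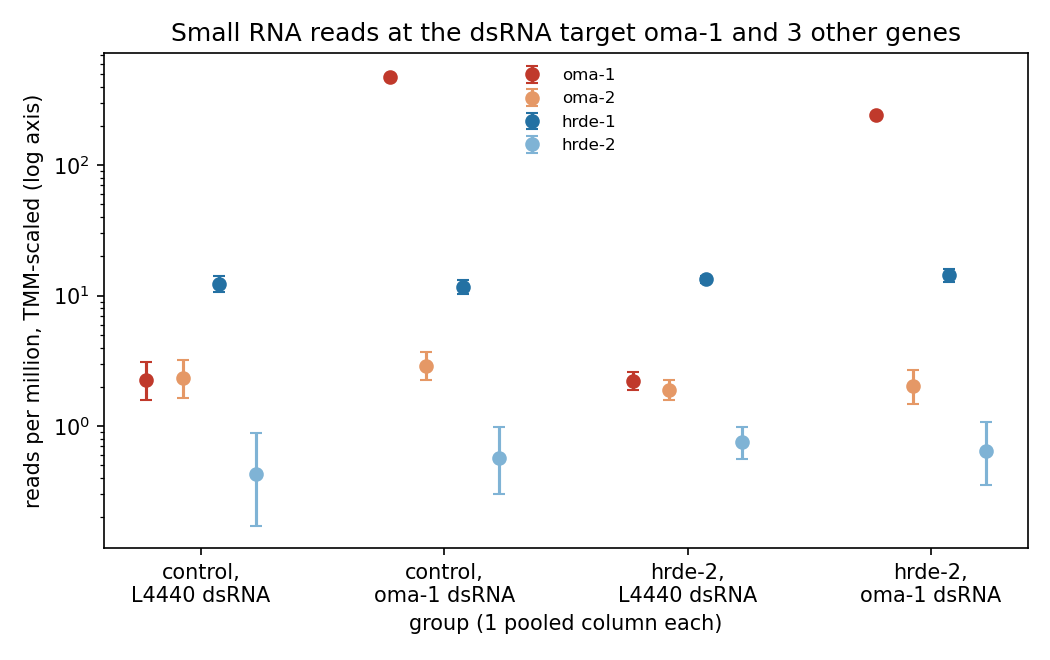
Small RNA reads at oma-1, oma-2, hrde-1 and hrde-2 in the 4 pooled columns, in TMM-scaled CPM on a log axis, with bars for the 95% counting interval. Reads at oma-1 stood at 2.26 and 2.22 CPM on L4440 and at 478 and 241 CPM on oma-1 dsRNA, in control and hrde-2 respectively.

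Few other genes differed between the dsRNAs in control animals. At 5 CPM or more in the higher group, 13 features were at least 2-fold higher on oma-1 dsRNA and 6 at least 2-fold lower. Among the 980 protein-coding genes without shared reads the numbers were 5 and 1. The 5 were oma-1 itself, clec-223 with 30 and 131 reads (ratio 3.14, 2.096 to 4.83), ZK666.1 with 33 and 124 reads (log2 1.43), unc-10, a gene of synaptic vesicle release, with 135 and 412 reads (log2 1.13), and R04A9.7 with 45 and 132 reads (log2 1.07). Y55F3C.17 was the 1 lower gene, with 185 and 92 reads (log2 −1.48). Y39F10C.1 and W08A12.3, at 1.16 and 1.08, had near-equal reads in every group. Under a filter of 10 CPM in at least 3 columns, 0 features were higher and 9 lower, and oma-1 was not among the features kept, being under that level in both L4440 columns.

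Several gene families shifted together by less than 2-fold in control animals on oma-1 dsRNA. Spermatogenesis genes had a median log2 difference of −0.50 over 77 genes, ribosomal protein genes −0.38 over 81, histone genes −0.41 over 72 and muscle genes −0.41 over 20. Each of these medians lay below all or nearly all of 10000 random lists of like abundance, at a percentile of 0. F-box genes stood at 0.36 over 213 genes and MATH, BATH and BTB genes at 0.23 over 76, at the 100th and 99.1th percentiles. Chemoreceptor genes stood at 0.24 (99.6th percentile) over 375 genes, with a range of 84.8 to 99.9 over the other scalings and filters. C-type lectin genes were at 0.20 (97.1th), neuronal genes at 0.25 (90.2th), cuticle collagen genes at 0.06 (82.2th), intestine genes at −0.09 (19.3th) and targets of the ERGO-1 26G pathway at 0.07 (72.2th). The medians of the spermatogenesis, ribosomal protein, histone, muscle, F-box and MATH, BATH and BTB lists kept their sign and their side of the random lists under all scalings tried without the strict filter.

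Among rRNA genes the 16 rrn-4 genes, which encode 5S rRNA, stood apart from the 4 genes of the larger rRNAs. In control animals the rrn-4 genes had a median log2 difference of 0.48 on oma-1 dsRNA, with 15 above 0, and the other 4 genes −0.55. In hrde-2 mutants the medians were −0.35 and 0.25. The share of all gene-assigned reads at rRNA genes went from 14.7 to 19.9% in control and from 14.8 to 10.3% in hrde-2. These numbers stand beside the shifts of the ribosomal protein, histone and muscle genes, which under TMM had the sign of the larger rRNA genes in both genotypes.

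In hrde-2 mutants 70 features were at least 2-fold higher on oma-1 dsRNA and 20 at least 2-fold lower. The highest after oma-1 at 20 CPM or more were mostly structural RNAs, among them C27H6.5 with 640 and 808 reads and the noncoding RNA W03A3.4 with 6605 and 6133 reads (log2 1.505). Of the 834 protein-coding genes without shared reads, 13 were higher and 8 lower. Higher were catp-2, a P-type ATPase gene (199 and 171 reads, log2 1.39), cysl-2, a gene of the cysteine synthase family (385 and 308 reads, log2 1.29), and bris-1 (244 and 191 reads, log2 1.255). The trio cutl-28, mab-20 and pyp-1 had near-equal reads, 2935 to 3043 on L4440, and log2 differences of 1.34, 1.34 and 1.32. Lower were K10C9.7 with 362 and 30 reads (log2 −1.97) and tra-3, a calpain gene of sex determination, with 458 and 52 reads (log2 −1.52). The lower genes lips-7, F48C5.2, pqn-73, snt-2 and fbxa-151 carried between 619 and 656 reads on L4440 and 79 to 88 on oma-1 dsRNA, and each had near-equal genes elsewhere.

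The split between higher and lower features in hrde-2 mutants turned with the scaling. It was 70 to 20 under TMM, 19 to 59 under library size alone and 5 to 137 under factors from miRNA genes. Relative to random lists of like abundance, ribosomal protein genes (median 0.36, 100th percentile) and histone genes (0.13, 99.5th) stood high in hrde-2 mutants on oma-1 dsRNA under every scaling tried, although their own medians reached −0.24 and −0.46 under other scalings. Intestine genes stood at 0.24 (98.96th), with the yolk protein genes vit-1 at 0.50 and vit-3, near-equal to vit-4, at 0.47. Under other settings the list ranged from the 84.9th to the 99.9th percentile, and its median from −0.34 to 0.27. Spermatogenesis genes were at −0.15 and targets of the ERGO-1 pathway at −0.23, both at or under the 0.1th percentile. F-box genes (−0.01, 62.8th), MATH, BATH and BTB genes (−0.03, 39.8th) and muscle genes (0.14, 94.4th) lay inside the central 95%.

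The next comparison asks whether the response to oma-1 dsRNA differed between genotypes. Taken as a ratio, the gain of oma-1 reads was smaller in hrde-2 mutants than in control by a log2 difference of −0.96 (counting standard error 0.265, interval −1.48 to −0.44). This value ranged from −1.497 to −0.94 over the scalings and filters tried. It lay inside the central 95% of the same difference over all features (−1.06 to 1.49) and over protein-coding genes (−1.10 to 1.23). On oma-1 dsRNA itself the oma-1 level was lower in hrde-2 by −0.99 under TMM, a ratio of 0.504 (0.488 to 0.521), but the value was 0.041 under library size alone. On L4440 the ratio of hrde-2 to control at oma-1 was 0.982 (0.681 to 1.45).

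Beyond oma-1, 225 features gained at least 2-fold more on oma-1 dsRNA in hrde-2 than in control and 70 at least 2-fold less, and most of the top ones were structural RNAs. This split turned with the scaling, to 82 and 302 under library size alone, 51 and 458 under miRNA factors and 111 and 175 under the authors' factors. F34H10.7, a noncoding RNA whose span holds a structural RNA, went from 676 to 354 reads in control and from 609 to 620 in hrde-2 (log2 3.05). Among the 1152 protein-coding genes without shared reads the numbers were 47 and 37. The genes with the larger gain in hrde-2 included catp-2, cam-1, a receptor tyrosine kinase gene of the Ror family (77, 75, 196 and 132 reads in the order of groups used for depth), and bris-1. The genes with the smaller gain included K10C9.7, Y55F3C.17, which had 149 reads on L4440 and 3 on oma-1 dsRNA in hrde-2, clec-223, ech-3 (log2 −1.20) and the chemoreceptor gene srd-49 (log2 −1.05). The pair col-102 and col-107 had near-equal reads and log2 differences of 1.56 and 1.55. By family the median difference was 0.82 for ribosomal protein genes, 0.56 for histone genes, 0.57 for muscle genes and 0.38 for spermatogenesis genes, and −0.47 for F-box genes and −0.38 for MATH, BATH and BTB genes. Structural RNAs moved in the direction of the first 4 families: tRNA genes had a median of 0.83, with 84 of 247 at least 2-fold higher and 0 lower, and the 4 larger rRNA genes 0.80, all above 0, while the rrn-4 genes had −0.83. Each median of the mRNA families lay outside the central 95% of random lists under all scalings tried without the strict filter; of these medians only that of spermatogenesis genes turned sign, to −0.15. Oogenic germline genes were at 0.30 (99.2th) and intestine genes at 0.39 (98.9th), and their medians turned to −0.24 and −0.15 under other scalings. Across the 2282 other features the dsRNA effects of the 2 genotypes correlated at a Pearson r of −0.17 and a Spearman rho of −0.24 across genes, which are not independent replicates.

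The genotype comparisons ask which endogenous small RNA targets differed in hrde-2 mutants, with and without the oma-1 trigger. On L4440, 281 of 2138 features were at least 2-fold higher in hrde-2 and 631 at least 2-fold lower. Among protein-coding genes without shared reads the numbers were 142 and 200 of 1040. On oma-1 dsRNA the numbers were 292 and 594 of 2130 features, and 146 and 259 of 1041 such genes. The split turned with the scaling: library size alone gave 1391 higher and 89 lower on L4440, and 932 and 95 on oma-1 dsRNA. The authors' factors gave 639 and 251, and 544 and 223.

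Of the genes higher in hrde-2 mutants, egl-4 (WBGene00001173, chromosome IV, 1848071 to 1880596), which encodes a cGMP-dependent protein kinase, had 158 and 203 reads in the control columns and 12128 and 2417 in the hrde-2 columns. The ratios were 18.8 (16.1 to 22.2) on L4440 and 12.4 (10.8 to 14.4) on oma-1 dsRNA. T16G12.4 had 29, 33, 1694 and 408 reads, log2 differences of 3.83 and 3.68, and F15D4.5 had 60, 100, 3161 and 944 reads, 3.69 and 3.30. The miRNA gene cel-mir-241 on chromosome V had near-equal reads to F15D4.5 (52, 87, 3063 and 948), so that the reads cannot be assigned to either. The genes clc-6, nhr-112 and C04E6.4 belonged to a band of 8 genes with near-equal reads, 1 to 12 in the control columns, 354 to 377 in hrde-2 on L4440 and 195 to 214 in hrde-2 on oma-1, so that their reads cannot be assigned to single genes and their ratios are not separate results. At clc-6, a claudin-like gene, the ratio was 30.8 (10.5 to 150.2) on L4440 and 224 (39.7 to 8868) on oma-1 dsRNA. At nhr-112, a nuclear hormone receptor gene, it was 88.8 (15.8 to 3518) and 53.5 (20.6 to 198). The chemoreceptor gene srz-70 had 5, 7, 548 and 326 reads, Y102A5C.36 had 7, 11, 942 and 224, and mab-20, a semaphorin gene, had 53, 61, 2953 and 2439 with the near-equal cutl-28 and pyp-1.

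Of the genes lower in hrde-2 mutants, acs-16 (WBGene00018579, chromosome I, 1471075 to 1479923), an acyl-CoA synthetase gene, had 1103 and 1352 reads in the control columns and 56 and 16 in the hrde-2 columns. The log2 differences were −6.30 on L4440 and −6.31 on oma-1 dsRNA. T14F9.2 on chromosome X had near-equal reads in every column (1100, 1313, 68 and 21). The C-type lectin gene clec-70 had 234, 206, 13 and 4 reads (log2 −6.09 and −5.51), near-equal to the pseudogene ZK783.6 (236, 219, 14 and 6), and the chemoreceptor gene sru-17 192, 293, 18 and 4 (−5.36 and −6.02). The sperm gene spe-18 had 239, 221, 34 and 9 reads (−4.80 and −4.50), and zyg-12, which joins centrosomes to the nucleus, 660, 879, 162 and 51 (−4.04 and −4.04). Lower as well were rsef-1 (−5.08 and −4.09), gst-43, a glutathione S-transferase gene (−4.13 on oma-1 dsRNA), and folt-3, a folate transporter gene (−4.04 and −3.17). The 44 features ranked highest and lowest by the mean over both foods under either naming rule, egl-4 and acs-16 among them, kept their sign at the scale of each setting tried, where a gene that a filter removed was still valued at that filter's scale. This says little, since a scaling moves all features alike. The median of unshared protein-coding genes for that mean went from 0.04 under TMM to 1.22 under library size. Features ranked by size, such as egl-4 and acs-16, could not turn sign under such a shift.

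**Figure D2:**
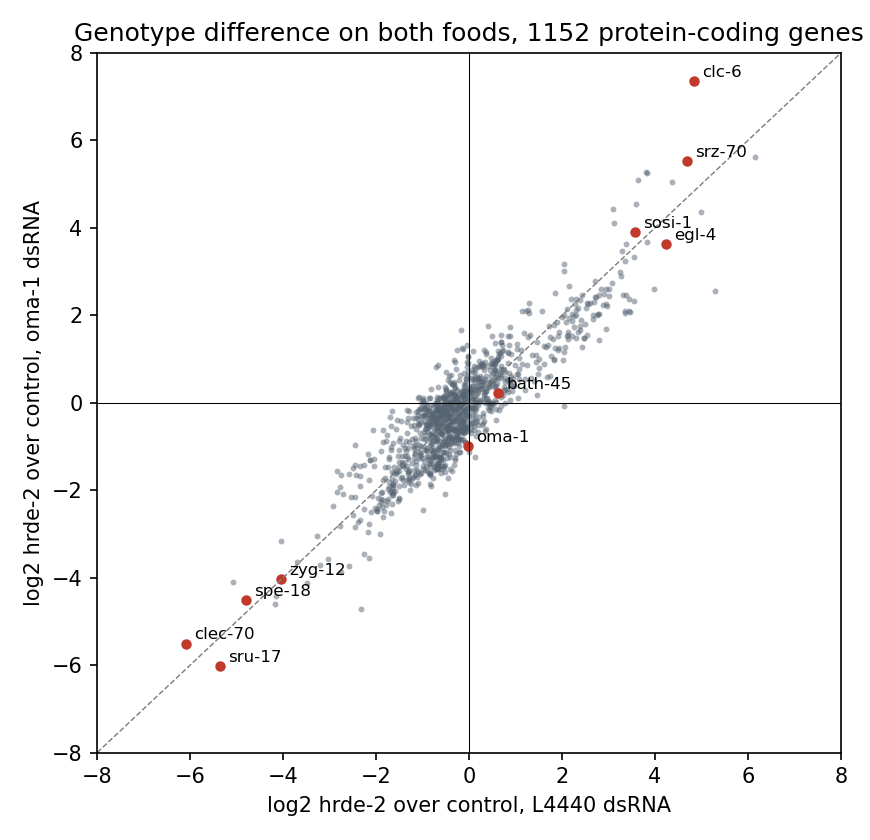
Each point is 1 of 1152 protein-coding genes not marked for shared reads (genes with few reads, such as clc-6, could not be marked by near-equal reads), placed by its log2 ratio of hrde-2 to control on L4440 (x axis) and on oma-1 dsRNA (y axis); the dashed line marks equal values and named genes are red. Points follow the line at a Pearson r of 0.901 across genes, from clec-70 at −6.09 and −5.51 to clc-6 at 4.83 and 7.37.

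The genotype difference had nearly the same form on both foods, in comparisons that share no column. Across 2283 features the log2 differences correlated at a Pearson r of 0.882 and a Spearman rho of 0.835, and across the 1152 protein-coding genes without shared reads at 0.901 and 0.838. These are correlations across genes, which are not independent replicates. At least 2-fold higher on both foods were 248 features, where 39.2 would fall together with no relation, and lower on both were 428 against 172. Only 1 feature lay 2-fold higher on 1 food and 2-fold lower on the other. The genotypes carried different 5′ barcodes, AGCG in control and CGTC in hrde-2, so that barcode and genotype cannot be told apart.

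Averaged over both foods, 283 features were at least 2-fold higher in hrde-2 and 650 lower, and 146 and 238 among protein-coding genes without shared reads. The additive fit of genotype and dsRNA left 1 residual degree of freedom, its spread being the departure between the foods, and took each pooled column as 1 sample. The quasi-likelihood test of edgeR called 1461 of 16329 features higher and 1584 lower in it at a Benjamini-Hochberg adjusted p below 0.05, with 1276 and 1153 of them at least 2-fold, and the Wald test of DESeq2 407 and 685. The split again turned with the scaling, to 10251 and 216 under library size alone. For dsRNA averaged over genotypes the edgeR test called 16 higher and 13 lower, oma-1 among the higher at a log2 difference of 7.201. The median genotype difference of protein-coding genes without shared reads, averaged over both foods, went down with abundance, from 0.24 under 1 CPM to −0.93 at 50 CPM or more. The count filter kept 10408 features on the control columns alone and 15794 on the hrde-2 columns alone. Many genes of low abundance may thus have been kept through the hrde-2 columns, where they are high. The family medians that follow are therefore set against random lists of like abundance, since the median of all 13226 such genes depended on the scaling. It was 0.04 on L4440 and 0.06 on oma-1 dsRNA under TMM, 1.4004 and 1.02 under library size, and 0.82 and 0.58 under the authors' factors.

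Spermatogenesis genes stood higher in hrde-2 mutants than random lists of like abundance on both foods, with medians of 0.57 on L4440 and 0.92 on oma-1 dsRNA over 77 genes, at the 100th percentile. Of these, 31 msp genes, which encode the major sperm protein, had medians of 0.57 and 0.96, with 31 and 30 of them above 0, and 46 other sperm genes had 0.73 and 0.80, with 35 and 36 above 0. The msp genes are near-identical in sequence, so that their reads cannot be assigned to single members, and spe-18 went the other way. Cuticle collagen genes had medians of 0.37 and 0.42 over 166 genes, at the 100th percentile, with 108 and 112 members above 0. Among the members at 5 CPM or more, fewer were 2-fold higher than 2-fold lower, 4 of 24 at least 2-fold higher and 9 lower on L4440, and 3 of 26 higher and 8 lower on oma-1 dsRNA; col-181, which had 2 near-equal genes, was at −2.29 and −2.05. The spermatogenesis and collagen lists kept this place and a median above 0 under all scalings tried. The strict filter left 6 collagen genes, which lay at the 51.8th and 88.5th percentiles, and too few spermatogenesis genes for that list to be placed. Chemoreceptor genes had medians of 0.71 and 0.52 over 375 genes, above the central 95% on both foods. Of the 9 members at 5 CPM or more, 3 were at least 2-fold higher and 4 lower on L4440, and 2 higher and 6 lower on oma-1 dsRNA, with srg-67 at 2.74 and 2.42 and srbc-38, which had a near-equal gene, at −1.32 and −1.31. The place of the list was not firm: under other scalings and filters their percentile went down to 82.9 and 68.1, and to 31.8 and 4.265 for the 5 genes left by the strict filter.

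Genes used as endogenous targets of HRDE-1 had medians of 0.56 and 0.64 over 6 genes, at the 97.8th and 97.9th percentiles. F15D4.5, C38D9.2 (57, 66, 1030 and 330 reads) and bath-45 (452, 819, 2837 and 912 reads) were higher in hrde-2 on both foods under TMM, and R03D7.2 was lower at −1.37 and −2.03. F15D4.5 and C38D9.2, at least 2-fold higher, each had a near-equal gene elsewhere (cel-mir-241 and Y46G5A.6), and bath-45, at 0.62 and 0.22, had none. This list was outside the central 95% in 6 of the 11 other settings on each food. Targets of the ERGO-1 26G pathway stood at 0.20 (99.1th) on L4440 and −0.06 (79.8th) on oma-1 dsRNA over 17 genes, and at the 99.99th and 98.63th percentiles for the 7 left by the strict filter, with C44B11.6 at 0.97 and 0.40 and E01G4.5 at −1.06 and −1.15. C-type lectin genes were at 0.54 (99.1th) and 0.39 (97.3th) over 130 genes, and under other settings at the 97.3th to 99.9th and the 81.4th to 98.7th percentile.

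Histone genes were lower in hrde-2 on L4440 than random lists of like abundance, with a median of −0.87 over 72 genes, 32 of them at least 2-fold lower, at a percentile of 0. On oma-1 dsRNA the median was −0.52 (8.36th percentile) with 24 genes lower; there the place went from the 0.92th to the 8.86th percentile under other settings and to the 57.55th under the strict filter, so that it depended on the setting. Under TMM structural RNAs were lower as well. For tRNA genes the medians were −1.53 and −0.60, and for snRNA genes −0.99 and −0.98. At least 2-fold lower were 175 of 246 tRNA genes on L4440 and 85 of 242 on oma-1 dsRNA. The share of gene-assigned reads at tRNA genes was 59.3% in control and 54.5% in hrde-2 on L4440. On oma-1 dsRNA it was 53.6% in control and 59.8% in hrde-2, so that the direction there depended on the scaling. The snRNA share on oma-1 dsRNA was 3.12% in control and 2.28% in hrde-2. Examples of histone genes were his-32 at −2.84 and −1.56 and his-14 at −2.75 and −1.65. The place below random lists on L4440 held under all scalings, while the median itself ranged from −0.88 to 0.53, and 33 of the 72 genes shared reads. The rRNA list was low on both foods, −1.59 and −2.41 over 20 genes, at the 1.32th and 0th percentiles, but 15 of its members shared reads, and under the strict filter, which kept 19, it lay at the 72.85th percentile on L4440 and the 0.245th on oma-1 dsRNA. Its rrn-4 genes had medians of −1.59 and −2.41 and the 4 larger rRNA genes −0.31 and 0.48.

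Ribosomal protein genes were at −0.23 (63.5th percentile) on L4440 and 0.52 (100th) on oma-1 dsRNA over 81 genes, and muscle genes at −0.03 (93.6th) and 0.46 (99.9th) over 20, with unc-54, a myosin heavy chain gene, at 0.13 and 0.70 and ttn-1, a titin gene, at 1.27 and 1.504. Intestine genes were at −0.30 (22.6th) and 0.29 (97.4th). Oogenic germline genes were at −0.36 (15.8th) and −0.06 (79.5th), with daz-1 at 2.54 and 1.83 and cgh-1 at −1.29 and −1.84; daz-1 had a near-equal gene and cgh-1 spans a structural RNA. Genes of small RNA pathways were at −0.07 (90.8th) and −0.08 (70.7th), with znfx-1 at −0.57 and −1.13. Mitochondrially encoded genes were at −0.92 (24.3th) and −0.47 (69.4th). Genes of chromosome segregation were at −0.31 (28.5th) and −0.26 (21.4th), neuronal genes at 0.10 (69.4th) and −0.10 (35.5th), F-box genes at 0.28 (96.5th) and 0.06 (33.7th), MATH, BATH and BTB genes at 0.13 (76.5th) and −0.09 (10.64th), and early zygotic genes at 0.08 (17.7th) and −0.15 (4.42th). Under the strict filter, which left 5 of them, ribosomal protein genes lay at the 0.875th and 84.82th percentiles. Of the short RNA classes, all 69 miRNA genes kept by the filter had medians of 0.08 and 0.32, and the 7 of them that the list matched by name were at 0.88 (93.6th) and 0.9996 (97.4th) and 71 piRNA genes at 0.48 (70.2th) and 0.73 (99.8th, and the 50th to 99.89th under other settings). Tested on the genotype term of the additive fit, camera called 7 of 22 lists at an adjusted p below 0.05. The lists of spermatogenesis, cuticle collagen and germline nuclear RNAi target genes were higher, and those of histone, rRNA, mitochondrially encoded and chromosome segregation genes lower. This test does not match lists for abundance, with which the genotype difference went down. The mitochondrially encoded and chromosome segregation lists lay inside the range of random lists of like abundance on both foods. Their calls cannot be told apart from an effect of abundance. The test also used a preset correlation, while the estimates for the called lists ran from −0.2 for germline nuclear RNAi targets to 0.515 for histone genes. With a correlation estimated per list camera called 0, and fry called 0. Both of these rest on the 1 residual degree of freedom of the fit, so that their 0 cannot decide whether the lists differ.

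**Figure D3:**
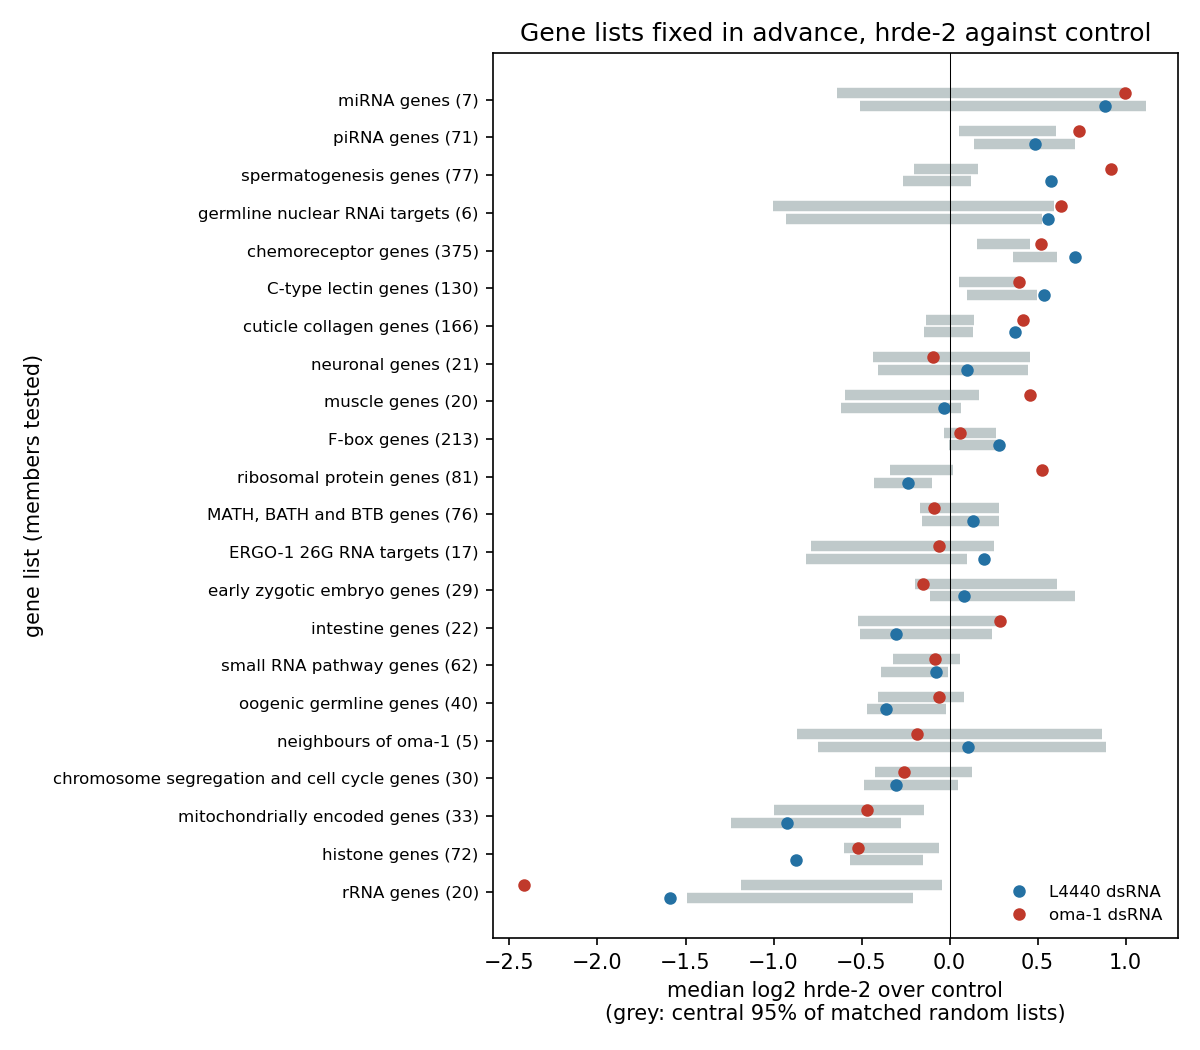
Median log2 ratio of hrde-2 to control for each gene list on L4440 (blue) and on oma-1 dsRNA (red), with grey bars for the central 95% of random lists of like abundance. Spermatogenesis genes (0.57 and 0.92) and cuticle collagen genes (0.37 and 0.42) lie right of both bars, and rRNA genes (−1.59 and −2.41) left of them.

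Reads at hrde-1 stood at like levels in the 4 groups under TMM, but not under every scaling, and reads at hrde-2 were few, so that its ratios have wide intervals. For hrde-1 (WBGene00007624, chromosome III) they numbered 201 and 266 in control and 887 and 312 in hrde-2, 12.3, 11.7, 13.3 and 14.3 CPM, and the mean log2 difference between genotypes was 0.20 under TMM and 1.42 under library size alone. For hrde-2 (WBGene00011324, chromosome V, 15005100 to 15006400) there were 7, 13, 50 and 14 reads, and the ratio of hrde-2 mutants to control was 1.75 (0.791 to 4.58) on L4440 and 1.12 (0.490 to 2.60) on oma-1 dsRNA, so that no difference was detectable at this depth under TMM. Under library size alone the ratios were 4.63 (2.09 to 12.1) and 2.30 (1.001 to 5.31), and under the authors' factors 3.07 (1.38 to 8.01) and 1.66 (0.723 to 3.83). A read number over a gene does not tell its allele.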

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

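All tests in this part were chosen only after the results they bear on had been seen.

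The share of reads at no annotated feature was 21.4% in hrde-2 on L4440 and 20.6% in hrde-2 on oma-1, above the 17.8% and 17.6% of the control columns; these reads are outside the comparisons. The effect of oma-1 dsRNA lay outside the central 95% of random lists on opposite sides in the 2 genotypes for 3 families, with a median log2 difference between genotypes of 0.56 for histone genes, 0.82 for ribosomal protein genes and −0.83 for rRNA genes. The last value is that of the 16 rrn-4 genes alone; the 4 larger rRNA genes stood at 0.80 and tRNA genes at 0.83, with histone and ribosomal protein genes, and whether RNA quality or library composition lies behind this common direction was not tested. The difference was not tested against a spread between samples, and under other scalings the hrde-2 medians of histone and ribosomal protein genes reached −0.46 and −0.24, the sign they had in control.

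The gain of oma-1 reads on oma-1 dsRNA was smaller in hrde-2 mutants than in control, by −0.96 on the log2 scale. Scaling alone is argued against, since the highest value over the scalings was −0.94, and so is counting error in the few oma-1 reads on L4440, since the upper limit of the interval was −0.44. The spread between samples stays open, as there was 1 column per group, and −0.96 lay inside the central 95% of the same difference over all features (−1.06 to 1.49). The lower oma-1 level of hrde-2 on oma-1 dsRNA, −0.99 under TMM, may by contrast come from the scaling, because it reached 0.041 under library size alone. The hrde-2 genotype remains an open, untested explanation of the smaller gain, as does the 5′ barcode that differs with it.

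The genotype difference was shared by both foods, at a Pearson r of 0.882 across features. Reads counted at more than 1 gene are argued against as the whole cause, since r was 0.901 across protein-coding genes not marked for shared reads and 0.915 across the 391 of them with enough reads for the mark. A shift that depends on abundance is also argued against, since r stayed at 0.895 after the median of each abundance bin was taken out. A library or barcode batch cannot be told apart from the genotype, because 0 of the 5′ barcodes were used in both. The hrde-2 genotype and other variants between the strains stay open.

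Among 1484 genes examined, 25 were at least 8-fold higher in hrde-2 on both foods and 19 at least 8-fold lower. A gene more than 10 kb away with near-equal reads existed for 52% of the higher genes (31.3 to 72.2) and 31.6% of the lower ones (12.6 to 56.6), against 56.1% and 66.9% of other genes of like read number; because other genes lie in a denser range of read numbers, a comparison with the genes' own reads times 0.7 to 1.3 was then chosen, which gave 23.0% and 3.95%. Shared reads may thus account for many of the higher genes, such as 8 genes (clc-6, nhr-112, hpo-36, C04E6.4, F09F3.8, F35E8.10, F35E8.13 and M60.6) with 354 to 377 reads in hrde-2 on L4440 and 195 to 214 on oma-1 dsRNA, though on the first of these comparisons neither set stood above other genes, and for the lower genes the matter stays open. Variants linked to hrde-2 are argued against as the whole cause, since 20.0% of the higher and 15.8% of the lower genes lay within 2 Mb of it. These 8 of 44 genes (18.2%, 8.19 to 32.7) are more than the 1.27 that the genes examined would give. Among them, however, F35E8.10, F35E8.13, F09F3.8 and nhr-112 belong to the genes with near-equal reads named above. C25D7.2 and C25D7.14 are pseudogenes close to each other. The interval takes all of them as independent, and the excess may count the same reads more than once. The hrde-2 genotype stays open as an untested explanation for the rest.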

How the results depend on the processing

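The authors' factors, the totals of all reads listed and of unshared protein-coding genes, leaving out shared genes and the 20 CPM minimum were chosen after the results had been seen, as were, for gene lists, all settings but library size, for the agreement between foods all but library size and the strict filter, and for hrde-1 all; the other settings were planned. No paired analysis was possible because the replicates of a group came in 1 pooled column, so that replicate numbers could not be a block or be left out, and the contrasts within 1 food or genotype and their difference could not be tested. With dsRNA as the block, an additive fit for the mean over foods was added after the results had been seen. In it edgeR called 3045 features (1461, 1584) at an adjusted p below 0.05, 2046 (994, 1052) below 0.01 and 2429 (1276, 1153) below 0.05 with 2-fold out of 16329 features, where the 933 counted by fold are out of the 2283 at 5 CPM, and DESeq2 called 1092 (407, 685). Camera called 7 of 22 lists with a preset correlation, and 0 with an estimated correlation (lowest adjusted p 0.739), as did fry (0.2101). The last 2 rest on the 1 residual degree of freedom, so that they cannot decide whether the lists differ. The median genotype difference of unshared protein-coding genes on L4440 and on oma-1 dsRNA was 0.04 and 0.06 under TMM, 1.4004 and 1.02 (library size), 0.82 and 0.58 (authors' factors) and 1.247 and 0.83 (all reads). Values below keep the order L4440, oma-1 dsRNA, mean of both, and numbers in brackets are higher and lower.

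Genotype counts were 912 (281, 631), 886 (292, 594) and 933 (283, 650). They were 421 (174, 247), 497 and 465 without shared genes and 498 (97, 401), 441 and 506 at 20 CPM, since fewer features were compared. The strict filter, which compared fewer features and also lowered the scale of hrde-2 on L4440 from 4.08 to 2.15 times that of control, gave 299 (144, 155), 245 (179, 66) and 246 (155, 91). Library size gave 1480 (1391, 89), with or without oma-1 and oma-2, then 1027 (932, 95) and 1318 (1252, 66). The authors' factors gave 890 (639, 251), 767 (544, 223) and 847 (625, 222), all reads 1249 (1132, 117), 878 (731, 147) and 1089 (982, 107), unshared protein-coding totals 814 (394, 420), 796 (50.5% higher) and 787 (407, 380), and miRNA factors 848 (382, 466) and 926 (211, 715) on the single foods.

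The dsRNA counts were 19 (13, 6) in control, 90 (70, 20) in hrde-2 and 295 (225, 70) for their difference. They were 10, 26 (18, 8) and 108 (59, 49) without shared genes, 7, 48 and 156 at 20 CPM, and 9 (0, 9), 23 (12, 11) and 111 under the strict filter. Leaving out structural RNAs gave 59 (40, 19) and 194 (121, 73) for the last 2. For these, miRNA factors gave 142 (5, 137) and 509 (51, 458), library size 78 (19, 59) and 384 (82, 302), the authors' factors 65 (32, 33) and 286 (111, 175), all reads 73 (18, 55) and 409 (68, 341), and unshared totals 84 (56, 28) and 255 (167, 88).

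For oma-1, the gain in hrde-2 was 6.75, and 6.16 with miRNA factors, 6.43 with library size or all reads and 6.48 with the strict filter. Its genotype difference on L4440 was −0.03, and 1.36 with library size, 0.89 with the strict filter, 0.77 with the authors' factors and 1.21 with all reads. On oma-1 dsRNA it was −0.99, and −1.23 with miRNA factors, −0.93 with only the columns compared, −0.88 with upper-quartile factors, −0.70 with unshared totals, −0.43 with the authors' factors, −0.16 with all reads, −0.14 with the strict filter and 0.041, above 0, with library size. The smaller gain was −0.96, and −1.497 with miRNA factors. For hrde-1 the mean genotype difference was 0.20, and 1.42 with library size, 1.24 with all reads, 1.09 with the strict filter, 0.89 with the authors' factors and 0.54 with unshared totals. The scale factors themselves make these differences; why the scalings disagree was not tested, and the cause was not tested either for the other changes.

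The strict filter also moved the agreement between foods from 0.882 to 0.785. It left 10 of the 22 lists with enough members to be placed. Lists outside random lists on both foods went from 5 to 1, which was the ERGO-1 list (99.99 and 98.63). Of the 5, the cuticle collagen, chemoreceptor and rRNA lists did not stay outside on both foods. The spermatogenesis and germline nuclear RNAi target lists had too few members left to be placed. Of the other values, 492 list percentiles kept their place, 21 moved outside the central 95%, 21 moved inside and 0 turned side; 3808 values of named genes moved by less than 0.5, 1241 moved further and 16 turned sign. Genes that a filter removed were valued at its scale. The 16 belong to 7 members named from lists, at least 2-fold lower under TMM. With library size, with or without oma-1 and oma-2, the values on L4440 were 0.3432 for E01G4.5, 0.1073 for cgh-1, 0.0055 for fbxb-14, 0.2967 for rps-17 and 0.0802 for srbc-38, and for the mean 0.065 for fbxa-103 and 0.1249 or 0.125 for rpl-41.2. With all reads E01G4.5 was at 0.187 and rps-17 at 0.1405. Of 89 differences of list members under 2-fold, 22 turned sign under some setting, and of the 224 differences of genes ranked highest or lowest 0. The last number says little, since these genes were ranked by the size of their difference and a scaling moves all features alike.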

Other observations

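The genes and classes in this part were chosen after the data had been seen, and no test was run on them.

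Single mitochondrial tRNA genes differed between genotypes, although the mitochondrially encoded genes as a list did not leave the range of random lists. Under TMM 28 of the 33 members were below 0 on L4440 and 26 on oma-1 dsRNA, where random lists of like abundance had medians of −0.77 and −0.55. MTCE.1 had 8899 and 12326 reads in control and 3420 and 2513 in hrde-2 (log2 −3.41 on L4440 and −2.23 on oma-1 dsRNA), and MTCE.10 had 1098, 2153, 448 and 245 (−3.32 and −3.07), while MTCE.32 was at 0.54 and 0.94. The miRNA gene cel-mir-241, of the let-7 family, had 52, 87, 3063 and 948 reads (3.85 and 3.50), near-equal to those at F15D4.5 and perhaps shared with it. The gene cel-mir-42 had 454, 366, 126 and 88 (−3.87 on L4440). Pseudogenes took 0.686 and 0.642% of gene-assigned reads in control and 1.304 and 1.29% in hrde-2, and long intergenic RNA genes 0.0504 and 0.0560% against 0.256 and 0.155%. On the TMM scale the larger share was not seen for pseudogenes, at 10618 and 9642 CPM in control and 7642 and 9524 in hrde-2, but it was for the sum of long intergenic RNA genes, at 780 and 842 against 1499 and 1140. This sum was not a common rise of its members. The median over 77 of them was 0.15 on L4440 and −0.10 on oma-1 dsRNA. Of 13 at 5 CPM or more, 1 was at least 2-fold higher and 1 lower on L4440, and 1 higher and 3 lower on oma-1 dsRNA. The snoRNA gene F28C6.11 was lower, with 1997, 2896, 456 and 297 reads, and Y38F2AR.14 higher, with 845, 1695, 33302 and 10770.

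Single members departed from their families. The F-box gene fbxa-56 had 151, 351, 3890 and 1260 reads (2.66 and 1.91) and fbxb-14 was at −1.39 and −1.89. The chemoreceptor gene sre-13, whose span holds a structural RNA, had 23195, 21020, 16347 and 9576 reads (−2.53 and −1.07). The gene sosi-1 had 12, 13, 593 and 191 reads (3.57 and 3.90). By chromosome, the median genotype difference of protein-coding genes without shared reads, averaged over both foods, was −0.01 on I, 0.02 on II, −0.05 on III, 0.06 on IV, 0.14 on V and 0.16 on X.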
